A study of Homo sapiens with 40 samples.

How the data were processed

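The cells were H1, an established human embryonic stem cell line, sampled before differentiation (day 0) and on days 3 and 5 of a mesoderm protocol in which BMP4, a growth factor of the TGF-beta family, was followed by bFGF, a fibroblast growth factor. On each day the cells were taken apart with successive buffers of a fractionation kit. Per the labels, the extracts were cytoplasmic (CE), membrane (ME), soluble nuclear (SNE), chromatin-bound nuclear (CBNE, freed with micrococcal nuclease) and the extract of the remaining pellet (PE), which the kit calls cytoskeletal. Libraries named INPUT were taken as RNA of cells that were not fractionated. Total RNA was sequenced in 36 libraries, 2 for each of 18 groups of day and fraction, and polyA RNA in 4 libraries of day 0 cytoplasm and nucleus, 2 each. Every library was assigned to its group from its title. Library numbers jump within day 5, which could be a separate batch (see Results).

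Both deposited tables hold TPM (reads per gene scaled by gene length to a fixed library total) as the authors computed it, with a column for each library. The unit is not named in the headers and was read from the values: total RNA columns summed to between 989513 and 998559, and polyA columns to between 1000000 and 1000000. Per the submitters' processing notes, HISAT2 2.0.5, GATK, featureCounts 1.6.2 and Salmon 1.3.0 were used with the hg38 genome, without a statement of which tool made which table. The total RNA table listed 57939 genes and the polyA table listed 58336. Gene identifiers were matched to GENCODE 29 on GRCh38, which held all identifiers of the total RNA table and 58216 of the polyA table, and coordinates, exon lengths and gene types were taken from it. A TPM value is a share of its library, so an abundant RNA that is present in an extract lowers the value of every other gene there. TPM does not give the amount of RNA per cell, and no spike-in was described.

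The tables hold no read numbers, and no count model was run. The number of reads behind each TPM value was estimated: TPM times gene length was taken as a multiple of the commonest such value in a library, which stands for 1 read. In polyA RNA 97.1% of the rebuilt numbers of up to 50 reads lay within 0.05 of a whole number. In total RNA 27.9% to 41.4% of the values of genes with a single annotated transcript lay within 0.01, so those depths are estimates. Depths are given in the results, and CE, ME, SNE and INPUT were deep. A read on a transcript of 1 kb equalled 0.707 to 1.81 TPM in the deep libraries, 13.8 to 16.8 in day 3 CBNE, 33.7 to 61.8 in day 0 and day 5 CBNE, 25.4 to 30.8 in day 0 PE, 6.60 to 7.25 in day 3 PE and 3.37 to 5.37 in day 5 PE. Pearson's r between replicates, on log2(TPM + 1) of genes at 1 TPM in either, ranged from 0.66 to 0.988, with the lowest values in CBNE and PE. No pair of replicate columns was a copy, since at least 15552 genes differed in each.

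The comparisons, tests, gene lists, the rule for named genes and a set of alternatives were fixed before the data were examined. Genes at 1 TPM or more in at least 2 libraries were tested, 24735 in total RNA and 16667 in polyA RNA, on log2(TPM + 1). A linear model with a mean for each group was fitted in limma 3.58.1 (R 4.3.3) with a trended, robust variance prior, with 18 residual degrees of freedom in total RNA and 2 in polyA RNA. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The localisation contrast set an extract against the mean of the other 4 extracts of the same day. The change contrast took the localisation on day 3 or day 5 minus that on day 0, which is the interaction of extract and day. INPUT was compared between days, and polyA nucleus with polyA cytoplasm. Fold changes are differences of mean log2(TPM + 1) and are pulled towards 0 for genes near or under 1 TPM. In the text, ± after a log2 value is its standard error, and ± after a TPM value or a percentage is the SD of the libraries.

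Shares of 10 RNA classes in the summed TPM of each library were compared between an extract (6 libraries) and the other extracts (24 libraries) with a two-sided exact permutation test of extract labels within days, adjusted over 50 combinations. Its 91125 permutations allow no p below 1.1e-05. Classes followed the GENCODE gene type, with histone and ribosomal protein mRNAs from the fixed lists, which are also counted within protein-coding RNA. Genes of microRNA precursors and of types outside these classes were not tested as classes.

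The 33 fixed gene lists covered RNA kinds (mitochondrial-encoded mRNA, nuclear lncRNA, cytoplasmic lncRNA, spliceosomal snRNA, structured RNA of RNA polymerase III, snoRNA and scaRNA), mRNA groups (replication-dependent histones, ribosomal proteins, nuclear-encoded oxidative phosphorylation, secreted and membrane proteins, cytosolic metabolism and translation, cytoskeleton, centrosome and spindle, immediate early genes, KRAB zinc finger proteins, stress and unfolded protein response), cell states (pluripotency, hESC lncRNA, primitive streak, lateral and cardiac mesoderm, paraxial and intermediate mesoderm, haemato-endothelial, definitive endoderm, neuroectoderm, neural crest and surface ectoderm, amnion and trophoblast) and programmes (EMT and matrix, epithelial junction, HOX, BMP response, WNT response, S and G2/M phase, cell cycle inhibitors and p53 targets). Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists and contrasts of a family, and again with an estimated correlation. Of 954 tests 435 passed with the preset and 137 with the estimated correlation. Members called within a list were also counted after adjustment over the list alone. Where no second count is given, the count adjusted over the list alone was the same.

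Named genes followed a rule. For each extract on day 0 they were the 6 protein-coding and 3 noncoding genes with the largest log2 fold change among those called higher on all 3 days, with both libraries above the 8 other extract libraries, a mean log2 value of at least 2 and a symbol that is not a clone name. For INPUT and polyA RNA they were the 12 highest and 12 lowest called genes, for changes between day 5 and day 0 the 3 largest per extract and direction, and for each list up to 4 called members per direction. MALAT1, NEAT1, GAPDH, ACTB, POU5F1, NANOG, TBXT, MIXL1, HAND1 and GATA4 were named in any case, and members that were not called only with their values. A few genes that met the rule are not reported here.

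The alternatives set beforehand were quantile normalisation, a shift of the log2 values to a common median (over 8014 genes at 1 TPM or more in all total RNA libraries), totals without structured and mitochondrial RNA, no filter on low values, a pseudocount of 0.1, INPUT as the reference, libraries of the same day only, the replicate number as a block, an adjusted p under 0.01, a mean of at least 4 for the comparison of tables, shares without mitochondrial-encoded genes, an estimated correlation, and leaving out each library. After the data were seen, further alternatives were added, namely genes with at least 5 expected reads at the depth of the least deep library compared, a variance for each group, a pseudocount of 1/2 read with weights by read number, INPUT libraries only, fits without the CBNE or the CBNE and PE libraries, SNE over CE only, and overlaps between days under a common median or that read minimum.

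The steps were tested on simulated data drawn at the real depths with a dispersion of 0.01. In INPUT, day 3 against day 0, genes changed 4-fold were called in 10.0% of cases and genes changed 2-fold in 0%. On day 0 a 4-fold rise was called in 52.0% of cases in CE, 48.0% in SNE, 54.0% in CBNE and 50.0% in PE, and a 4-fold drop in 24.00%, 26.0%, 68.0% and 58.0%. The genes left alone in those draws gave 422 calls in CE, 429 in SNE, 4293 in CBNE and 3271 in PE, so single-gene calls in every extract include calls that the depth alone gives, mostly lower ones in CBNE and PE. Draws with no localisation are given in the results. In polyA RNA a 4-fold rise was called in 99.0% of cases and a 2-fold rise in 38.0%. Camera was tested apart, on 5000 genes of independent random normal values without depth or inter-gene correlation. It called 20 of 20 raised lists and 1 of 20 unchanged lists there, which cannot judge the preset correlation. Class shares, rebuilt reads and counts were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Of the lists, structured RNA, snRNA and snoRNA kept few members at the filter, since many of their genes were listed at or near 0. Isoforms, splicing and intron reads could not be measured from gene tables and were left out.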

Results

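The series asked in which part of H1 embryonic stem cells each RNA lay, from day 0 through days 3 and 5 of mesoderm differentiation. Each day had 5 extracts, namely cytoplasmic (CE), membrane (ME), soluble nuclear (SNE), chromatin-bound nuclear (CBNE) and pellet (PE), beside RNA that was not fractionated (INPUT). All groups had n = 2, in 36 libraries (18 groups) of total RNA and 4 of day 0 polyA RNA. In day 0 INPUT, mRNA of the pluripotency factor POU5F1 stood at 80.9 ± 2.54 TPM and that of the mesoderm factor HAND1 at 0.740 ± 0.389 TPM. By day 5 they stood at 36.2 ± 2.05 and 787 ± 30.0 TPM. The labels do not say that replicates were separate cultures, so p-values of single genes measure the spread between these libraries. The test of class shares relabels single libraries, and the list test sets members against other genes. Neither measures the spread between cultures.

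Depth differed between extracts. CE, ME, SNE and INPUT libraries held an estimated 904906 to 1815620 gene reads, PE libraries 37037 to 471910 and CBNE libraries 19599 to 90433, while polyA libraries held 14449217 to 17270359. In day 0 and day 5 CBNE a single read on a 1 kb transcript already gave 33.7 to 61.8 TPM. The extracts also differed in composition and in the level of the median gene, and how far the former sets the latter was not tested. On day 0 the log2 contrast of the median gene with the other 4 extracts was 0.02 in CE, -0.53 in ME, 0.99 in SNE, 0.01 in CBNE and -0.60 in PE. Counts of genes are therefore given beside their values under other scalings, and the text leans on RNA classes, gene lists and abundant genes. The comparisons, tests and lists were chosen before the data were examined. Some alternatives, listed above, and the draws with no localisation were added later.

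**Figure D1:**
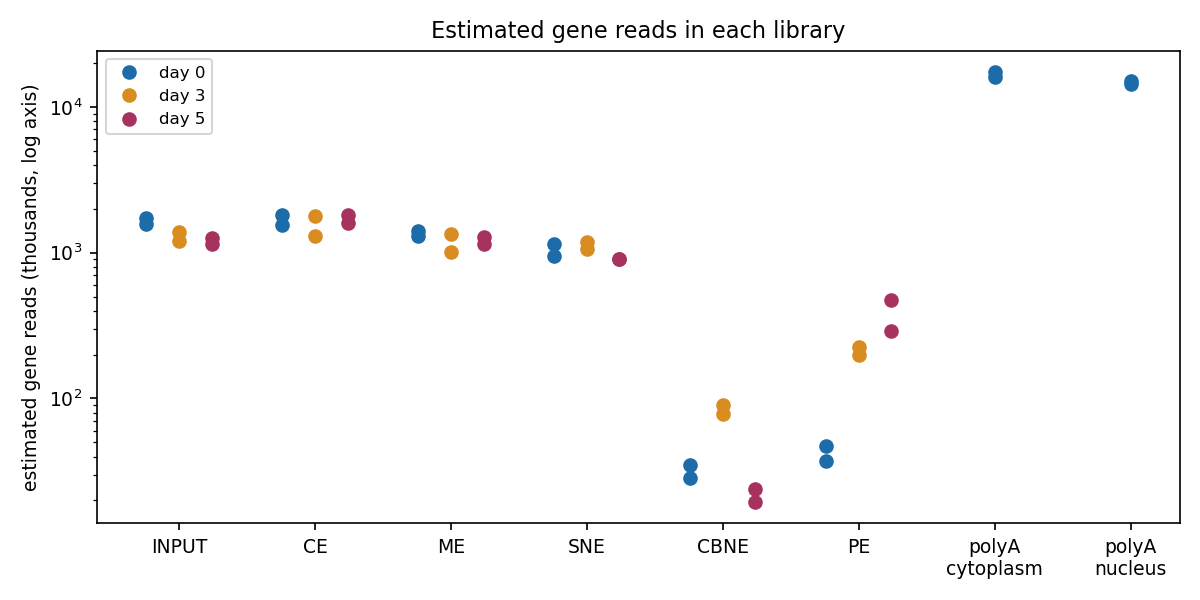
Estimated gene reads in each library (shown in units of 1000, log axis) by group. The day 5 CBNE libraries were the least deep, from 19599 to 23990 reads.

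The extracts carried distinct RNA. Transcripts of the mitochondrial genome, made inside the organelle, took 53.01% ± 6.46 of summed TPM in ME against 13.4% ± 10.3 in the other extracts (adjusted p = 1.1e-04, exact permutation test within days, 6 against 24 libraries) and 1.63% ± 0.187 in CE (adjusted p = 0.0154). CE held the largest share of protein-coding RNA, 84.3% ± 0.784 against 46.9% ± 10.8 (adjusted p = 1.1e-04, exact test). With mitochondrial-encoded genes left out of the totals the gap was smaller, 85.7% ± 0.818 against 66.3% ± 16.6 (adjusted p = 0.0284, exact test). Replication-dependent histone mRNAs, which end in a stem-loop in place of a polyA tail, took 8.56% ± 0.575 of CE against 1.00% ± 0.497 elsewhere (adjusted p = 1.1e-04), and ribosomal protein mRNAs 8.53% ± 0.676 against 1.90% ± 0.786 (adjusted p = 1.1e-04). Pseudogenes followed the same course in CE, 8.07% ± 0.442 against 4.39% ± 1.67 (adjusted p = 4.1e-04), and share sequence with their parent mRNAs.

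Long noncoding RNA leaned to the soluble nuclear extract. Its share was 9.56% ± 1.64 in SNE against 6.25% ± 3.05 in the other extracts (adjusted p = 0.0459, exact permutation test) and 3.47% ± 0.955 in CE (adjusted p = 0.00210). The class includes FP236383.3 and FP671120.4, which lie in the 45S ribosomal DNA units. Genes of these units took 4.84% of day 0 CBNE and 6.58% of day 0 PE, but 0.0131% of day 0 CE. The lncRNA shares of these groups were 9.48%, 10.6% and 4.69%. The low call of CE may thus rest partly on these genes, and shares without them were not tested. Small nuclear RNAs of the spliceosome, listed at low levels in these libraries, took 0.398% ± 0.0728 of SNE (adjusted p = 4.3e-04) and 0.0450% ± 0.0606 of CBNE (adjusted p = 3.7e-04). Small nucleolar RNAs, guides of ribosomal RNA processing, made up 14.7% ± 8.08 of CBNE against 1.45% ± 2.99 (adjusted p = 1.1e-04), and the class of 7SK, 7SL and other structured RNAs 8.13% ± 0.839 against 2.00% ± 2.13 (adjusted p = 3.9e-04). Ribosomal protein mRNAs made up 0.892% ± 0.140 of CBNE (adjusted p = 0.0489), and rRNA genes 0.0733% ± 0.0243 of PE against 0.0248% ± 0.0252 (adjusted p = 0.00210). In all 16 of 50 combinations passed. ME had low shares of lncRNA, 3.61% ± 0.663 (adjusted p = 0.00800), and of protein-coding RNA, 37.9% ± 6.80 (adjusted p = 0.0365), which rested on its mitochondrial load. With mitochondrial-encoded genes left out of the totals ME held 7.92% ± 2.40 lncRNA against 9.25% ± 3.85 (adjusted p = 0.470) and 80.2% ± 3.97 protein-coding RNA against 67.6% ± 17.8 (adjusted p = 0.187), so neither call held and the latter turned in direction.

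**Figure D2:**
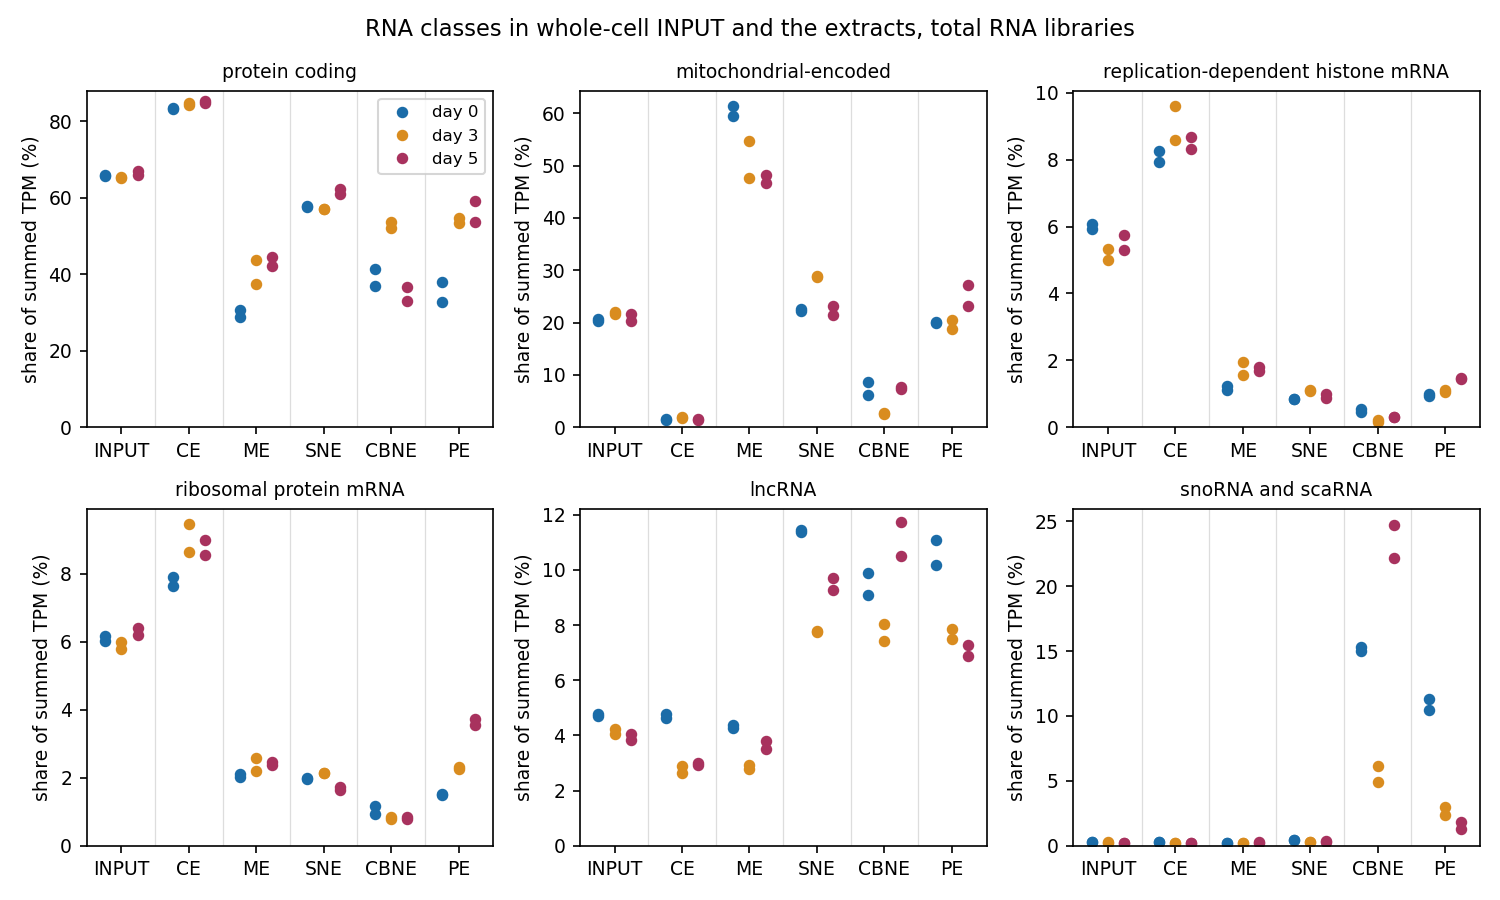
Share of summed TPM (%) of 6 RNA classes in INPUT and the 5 extracts, a point per library, coloured by day. Mitochondrial-encoded RNA made up 60.5% of ME on day 0, 51.2% on day 3 and 47.4% on day 5.

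Day 0 INPUT showed what the extracts divided between them: 65.8% ± 0.183 protein-coding RNA, 20.5% ± 0.277 mitochondrial RNA and 4.73% ± 0.0556 lncRNA (n = 2). Within protein-coding RNA, ribosomal protein mRNA took 6.08% ± 0.0994 and histone mRNA 6.01% ± 0.107 of the library. Mitochondrial RNA made up 60.5% ± 1.27 of ME on day 0. In CBNE the snoRNA share was 15.2% ± 0.234 on day 0, 5.51% ± 0.852 on day 3 and 23.4% ± 1.82 on day 5, and in PE it was 10.9% ± 0.606, 2.65% ± 0.426 and 1.54% ± 0.413. These shares were not tested between days.

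The cytoplasmic extract of day 0 was rich in mRNAs of housekeeping and growth. GAPDH, a glycolytic enzyme, stood at 6792 ± 94.2 TPM in CE, 997 ± 48.6 in ME, 882 ± 9.84 in SNE, 433 ± 75.8 in CBNE and 1091 ± 15.1 in PE (log2 3.08 ± 0.09 for CE against the mean of the other 4 extracts). POU5F1 mRNA was called higher in CE as well (3.87 ± 0.25; 129.6 TPM in CE, 12.6 in ME, 12.8 in SNE, 1.03 in CBNE and 18.7 in PE), although its pseudogenes share sequence with it. Histone genes led, with 33 of 34 tested members called higher (adjusted p = 5.7e-11, camera). Among them were H4C13 (5.92 ± 1.55; chromosome 6, 27873199 to 27873510), H3C1 (5.28), H2BC3 (5.02), H2AC4 (4.79) and H4C6 (5.78). Ribosomal protein mRNAs were called higher for 69 of 74 (adjusted p = 3.8e-35), among them RPL15 (3.70 ± 0.19), RPS3A (3.34) and RPL29 (3.32).

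CE was also high in nuclear-encoded mRNAs of the respiratory chain, 39 of 46 called higher (adjusted p = 2.1e-15), such as UQCRQ (4.96) and NDUFA1 (4.34). Transcripts of the mitochondrial genome itself stood lower in CE, 13 of 13 (adjusted p = 9.5e-16). Metabolic and translation mRNAs (29 of 31 higher, adjusted p = 2.9e-21) included LDHA (3.69) and PGAM1 (3.44), and chaperones of the stress list (16 of 20, adjusted p = 2.9e-07) included SDF2L1 (4.15). The short mRNAs SMIM30 (5.09) and NOP10 (5.07) and the pseudogenes TMSB4XP8 (8.08), RPL21P16 (6.74) and RPL41P1 (6.57) headed the genes high on all 3 days. Reads of such pseudogenes cannot be told from those of their parents.

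Other lists passed in CE with the preset correlation alone. Pluripotency mRNAs gave 17 higher and 1 lower of 35 (adjusted p = 1.2e-05, and adjusted p = 0.101 with an estimated correlation), with GDF3 (3.75), LIN28A (2.80) and NANOG (2.31) higher and TERT lower (-1.50). Cytoskeleton mRNAs divided, with TUBA1B (4.11) and ACTB (2.10) higher and DST (-1.71) and PLEC (-1.80) lower, 23 higher and 2 lower of 45 (adjusted p = 1.8e-06, and adjusted p = 0.146 with an estimated correlation). S and G2/M phase mRNAs gave 26 higher and 2 lower of 38 (adjusted p = 3.0e-07, and adjusted p = 0.148 with an estimated correlation), among them CDC20 (3.48) and MKI67 (-1.27). Epithelial genes such as CLDN6 (3.49) gave 11 of 25, or 13 adjusted over the list alone, higher (adjusted p = 4.8e-05, and adjusted p = 0.0669 with an estimated correlation), and spliceosomal snRNA genes 11 of 17 (adjusted p = 0.0123, and adjusted p = 0.0878 with an estimated correlation).

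Noncoding RNA in day 0 CE divided. The cytoplasmic lncRNAs NORAD (3.00) and SNHG16 (2.97) were called higher and TMEM161B-AS1 lower (-3.04), 5 higher and 1 lower of 15 on their list (adjusted p = 0.0305, and adjusted p = 0.181 with an estimated correlation). Of the nuclear lncRNAs TUG1 was higher (1.66) and PVT1 (-1.89) and FIRRE (-1.63) lower, 1 higher and 4 lower of 15 (adjusted p = 0.00426, and adjusted p = 0.274 with an estimated correlation). KRAB zinc finger mRNAs, from a large family of repressors of transposons, gave 2 higher and 11 lower of 37 (adjusted p = 9.0e-04, and adjusted p = 0.381 with an estimated correlation), with ZNF254 at -2.10.

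On days 3 and 5 the same families marked CE: histones 32 of 34, or 33 adjusted over the list alone, and 32 of 34 higher (adjusted p = 6.0e-19 and 4.6e-16), ribosomal proteins 70 of 74 and 70 of 74 (adjusted p = 3.0e-53 and 3.5e-43). Genes switched on by differentiation joined them on day 5, when primitive streak mRNAs were called higher for 19 of 27, or 20 adjusted over the list alone, and lower for LEF1 (-1.53; adjusted p = 4.7e-08), including DKK1 (3.17), CYP26A1 (2.96), MIXL1 (2.91) and TBXT (1.82). Endoderm mRNAs CER1 (2.50) and SOX17 (2.50) were higher too (7 of 14, adjusted p = 0.00115), and so was HAND1 (2.26 on day 3, 2.07 on day 5). Over all genes, 4645, 2583 and 3082 higher and 2116, 4884 and 4356 lower were called on days 0, 3 and 5. Quantile normalisation gave 3447, 3060 and 3412 higher and 3134, 2632 and 2987 lower, a common median 4302, 4715 and 4953 higher and 2468, 1989 and 2326 lower, and totals without structured and mitochondrial RNA 2653, 1503 and 1773 higher and 4953, 7213 and 6848 lower. The families above kept their direction under the common median. Against INPUT in place of the other extracts day 0 CE had only 14 higher and 158 lower, so few genes were called above the whole cell in CE.

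The membrane extract was dominated by transcripts of the mitochondrial genome. MT-ND2, a subunit of respiratory complex I (the mitochondrial genome, 4470 to 5511), stood at 738 ± 15.6 TPM in CE, 42967 ± 2071 in ME, 12937 ± 396 in SNE, 2853 ± 556 in CBNE and 7324 ± 181 in PE on day 0 (log2 3.52 ± 0.10). MT-ND3 (3.39), MT-CYB (3.36), MT-ND1 (3.30), MT-ND4 (3.30) and MT-ATP6 (3.22) followed. The list had 13 of 13 higher (adjusted p = 1.0e-30), with a median of 2.92, which is 3.45 above the median gene, and on days 3 and 5 13 of 13 and 12 of 13, or 13 adjusted over the list alone (adjusted p = 1.2e-32 and 6.1e-28). The mitochondrial tRNA gene MT-TT (8.44) and the pseudogenes COX6A1P2 (5.06) and MTCO1P12 (4.07), the latter a copy of MT-CO1, were high on all 3 days.

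Messages of secreted and membrane proteins, translated at the endoplasmic reticulum, were a smaller part of ME. SCD, a lipid desaturase of that membrane, stood at 1317 TPM in CE, 633 in ME, 314 in SNE, 35.1 in CBNE and 98.9 in PE on day 0, so its call in ME (1.73) was against the mean of the other 4 extracts and CE held more. Against the same mean SLC2A3 (1.35), NOTCH2 (1.27) and COL4A1 (1.24) were higher as well, while LAMA5 was lower (-1.05). The list gave 9 higher and 1 lower of 83 (adjusted p = 4.2e-06, and adjusted p = 0.397 with an estimated correlation) on day 0. It gave 8 higher and 3 lower of 83 on day 3 (adjusted p = 2.6e-07, and adjusted p = 0.347 with an estimated correlation). Day 5 had 14 higher and 1 lower of 83 (adjusted p = 1.3e-17, and adjusted p = 0.148 with an estimated correlation), when the chaperones HSPA5 (1.81) and PDIA3 (1.39) led. With a common median the counts were 28 higher and 0 lower, 43 higher and 0 lower, and 49 higher and 0 lower. That setting aligns the median gene whatever moved it and does not remove the mitochondrial load.

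Further lists passed in day 0 ME. The snoRNA list had 3 of 4 lower (adjusted p = 0.00160), with SNORD3A at -3.12. Cytoskeleton mRNAs gave 1 higher and 10 lower of 45 (adjusted p = 3.0e-04, and adjusted p = 0.236 with an estimated correlation), and 3 higher and 1 lower under a common median. Respiratory chain mRNAs gave 6 higher and 3 lower of 46, or 9 and 3 adjusted over the list alone (adjusted p = 0.0329, and adjusted p = 0.337 with an estimated correlation), and 16 higher and 0 lower under a common median. Embryonic stem cell lncRNAs gave 1 higher and 2 lower of 14 (adjusted p = 0.0213, and adjusted p = 0.201 with an estimated correlation) and 5 higher and 1 lower with a common median. That setting shifts all genes alike, so the direction of these lncRNA and cytoskeleton calls depended on the scale. On day 5 histone mRNAs stood above other genes in ME (4 of 34 called higher, adjusted p = 1.1e-06). Over all genes ME had 654, 486 and 604 higher and 2349, 4321 and 2869 lower called on days 0, 3 and 5. Other scalings gave 1739, 1631 and 1631 higher and 1304, 1113 and 1075 lower (quantile normalisation) and 2370, 3170 and 2769 higher and 664, 495 and 414 lower (common median). Totals made anew gave 4186, 1832 and 1945 higher and 370, 1215 and 1090 lower without structured and mitochondrial RNA. Libraries drawn with no localisation gave 414, 84 and 204 higher calls for ME, so depth alone matches a large part of the higher calls of day 0. The same draws gave 375, 76 and 221 higher calls for CE and 400, 79 and 231 for SNE.

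The soluble nuclear extract held the known nuclear lncRNAs. MALAT1, a nuclear speckle RNA, stood at 2181 ± 6.34 TPM in CE, 3189 ± 28.8 in ME, 9577 ± 207 in SNE, 1319 ± 215 in CBNE and 3149.6 ± 965 in PE on day 0 (log2 2.06 ± 0.11). NEAT1, the scaffold of paraspeckles, stood at 33.1 TPM in CE, 62.5 in ME, 175 in SNE, 27.8 in CBNE and 49.0 in PE (2.08 ± 0.17). KCNQ1OT1 (2.56), FTX (2.84), TUG1 (2.27) and MIAT (2.16) were higher as well, 10 of 15 on the list (adjusted p = 0.0309, and adjusted p = 0.392 with an estimated correlation). Days 3 and 5 gave 12 of 15 (adjusted p = 7.3e-05, and adjusted p = 0.148 with an estimated correlation) and 12 of 15 (adjusted p = 5.2e-04, and adjusted p = 0.193 with an estimated correlation), and on day 5 NEAT1 reached 2653 TPM in SNE against 110.5 in CE (3.16). Since the median gene lay 0.99 above the other extracts in day 0 SNE, MALAT1 came to 0.99 and NEAT1 to 1.01 with a common median, and the list to 6 higher and 3 lower.

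KRAB zinc finger mRNAs gave 25 of 37 higher in day 0 SNE (adjusted p = 4.8e-06, and adjusted p = 0.236 with an estimated correlation), with ZNF117 (2.41) and ZNF90 (2.38), and 3 higher and 1 lower with a common median. The snoRNA hosts GAS5 (3.36), SNHG1 (3.46) and ZFAS1 (2.99) were called higher, although their list, that of cytoplasmic lncRNAs, did not pass (adjusted p = 0.144). The stem cell lncRNA LINC01108 (3.71), the coding genes RABGGTB (3.75 ± 0.54, itself a host of snoRNAs), CAVIN4 (3.86), TAS2R5 (3.78), VWDE (3.62), KCNT2 (3.60) and EXTL2 (3.60), and the mitochondrial MT-ND6 (3.17) were among the largest.

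Histone mRNAs stood lower in day 0 SNE, 6 of 34 (adjusted p = 9.7e-09), as did the snoRNA list, 3 of 4 (adjusted p = 1.5e-06). Ribosomal protein mRNAs gave 8 higher and 7 lower of 74 on day 0 (adjusted p = 8.7e-09, and adjusted p = 0.0940 with an estimated correlation; 0 higher and 40 lower with a common median) and 20 of 74 lower on day 5 (adjusted p = 1.0e-31). Paraxial mesoderm genes passed as a list on day 0 (adjusted p = 0.00372, below other genes) at low levels. Secretory mRNAs showed how far scaling matters, with 29 higher and 3 lower of 83 as deposited but 5 higher and 23 lower with a common median. That setting shifts all genes alike, so the turn is one of scale and not a result about these mRNAs. Their list did not pass (adjusted p = 0.802, camera). Over all genes SNE had 9719, 6081 and 8659 higher and 501, 579 and 411 lower on the 3 days. Quantile normalisation gave 3166, 2337 and 3118 higher and 2572, 1844 and 2255 lower, and a common median 2699, 1983 and 2571 higher and 4944, 2684 and 4880 lower. Totals without structured and mitochondrial RNA gave 8446, 6658 and 8021 higher and 760, 500 and 535 lower, and the minimum of 5 expected reads 310, 792 and 119 higher and 117, 221 and 68 lower. The surplus of higher genes was thus kept by these last settings and shrank or turned under those that align the values or medians.

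The extract labelled chromatin-bound was marked by U3 small nucleolar RNA. It was freed with micrococcal nuclease, whose effect on RNA was not tested, so its content does not show binding to chromatin. SNORD3A, the U3 snoRNA of the early pre-rRNA processing complex (chromosome 17, 19188016 to 19188714), stood at 1795 ± 33.8 TPM in CE, 1574 ± 32.4 in ME, 1796 ± 33.8 in SNE, 123312 ± 6562 in CBNE and 88683 ± 7240.4 in PE (log2 4.74 ± 0.13). Its copies SNORD3B-1 and SNORD3C were at 6.58 and 5.72, and SNORD13 was lower (-4.87). The list had 3 higher and 1 lower of 4 (adjusted p = 0.00154), and the same counts on day 3 (adjusted p = 0.0164, and adjusted p = 0.0940 with an estimated correlation) and day 5 (adjusted p = 6.4e-04). Copies of U3 share reads, so their single levels are uncertain. P-values of this list, in any extract, count these copies as separate genes. SNORD3A alone held most of the day 0 snoRNA share of 15.2% in CBNE. RN7SL3, a 7SL copy of the signal recognition particle, was called higher (2.66 ± 0.12; 9038 TPM in CE, 5813 in ME, 3197 in SNE, 64344 in CBNE and 64417 in PE), while its list of structured RNAs did not pass (adjusted p = 0.956).

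Messages of the cytoplasm were low in CBNE. Histones gave 26 of 34 lower (adjusted p = 2.0e-04). Ribosomal proteins gave 2 higher and 51 lower of 74, or 2 and 52 adjusted over the list alone (adjusted p = 8.4e-12, and adjusted p = 0.0515 with an estimated correlation). Respiratory chain mRNAs gave 3 higher and 27 lower of 46 (adjusted p = 0.00331, and adjusted p = 0.201 with an estimated correlation), and metabolic mRNAs 2 higher and 20 lower of 31 (adjusted p = 3.5e-05, and adjusted p = 0.220 with an estimated correlation). Mitochondrial transcripts were lower for 9 of 13 (adjusted p = 0.00282, and adjusted p = 0.382 with an estimated correlation) and stress mRNAs for 11 of 20 (adjusted p = 0.0185, and adjusted p = 0.174 with an estimated correlation). Stem cell lncRNAs gave 2 higher and 9 lower of 14, or 2 and 10 adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.170 with an estimated correlation), with LNCPRESS1 higher (1.72). GAPDH (-1.89) and MALAT1 (-1.53) were lower. POU5F1 (-3.91) was too, but at under 1 read, so its value is a floor. Days 3 and 5 had histones lower for 32 of 34 and 31 of 34 (adjusted p = 8.9e-10 and 1.3e-05) and ribosomal proteins for 59 of 74 and 67 of 74, or 68 adjusted over the list alone (adjusted p = 5.2e-23 and 9.5e-16).

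Genes high in CBNE on all 3 days were headed by MIR4787 (5.06), PRKXP1 (5.05) and the coding genes CLDN20 (4.29), NAA10 (4.21), AKR1C1 (4.14), ZC4H2 (3.74 ± 0.12; chromosome X, 64915802 to 65034713), TMEM191B (3.73) and HYAL1 (3.47), most of them at few expected reads. All genes together gave 2979, 4863 and 2823 higher and 6149, 4808 and 8039 lower on days 0, 3 and 5, a common median 3078, 3327 and 3397 higher and 6035, 6777 and 6982 lower and quantile normalisation 4919, 5210 and 5447 higher and 4128, 4347 and 5043 lower. Libraries drawn at the real depths with no localisation gave 4110 lower and 379 higher calls for day 0 CBNE, 1133 and 130 for day 3 and 6302 and 398 for day 5. Among the 928 genes with at least 5 expected reads on day 0, 193 higher and 390 lower were called.

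The pellet extract shared the U3 snoRNA with CBNE. SNORD3A stood at 4.15 ± 0.13 on day 0, and the list gave 3 higher and 1 lower of 4 (adjusted p = 3.5e-06). Mitochondrial transcripts such as MT-CO1 (1.42) and MT-CO3 (1.24) were higher for 5 of 13 (adjusted p = 1.1e-09, and adjusted p = 0.101 with an estimated correlation). The cytoskeleton list had 4 higher and 6 lower of 45 and did not pass (adjusted p = 0.323). Of its members called higher PLEC, a linker of intermediate filaments, was at 57.7 TPM in CE, 98.2 in ME, 124 in SNE, 306 in CBNE and 471 in PE (1.95). TPM2 (1.92), ACTN4 (1.81) and MYH9 (1.27) were the others, and the matrix genes LAMA5 (2.15), AGRN (1.93) and COL18A1 (1.81) were higher too. MKI67 (1.54) and ANKRD11 (1.73) were called higher.

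Early response genes IER5 (2.19), EGR3 (1.95), JUND (1.86) and ZFP36 (1.49) were called higher in day 0 PE, 5 higher and 4 lower of 29 on the list (adjusted p = 0.0124, and adjusted p = 0.391 with an estimated correlation). Endothelial genes SOX18 (3.05), HHEX (2.17) and ETV2 (2.03) were higher and KDR lower (-1.51; 5 higher and 1 lower of 23, adjusted p = 0.00844), at few expected reads. Respiratory chain mRNAs were lower for 29 of 46 (adjusted p = 3.0e-05, and adjusted p = 0.0899 with an estimated correlation), and ribosomal proteins gave 1 higher and 33 lower of 74 (adjusted p = 1.9e-05, and adjusted p = 0.194 with an estimated correlation). As deposited, so were metabolic mRNAs (1 higher and 17 lower of 31, adjusted p = 7.0e-05, and adjusted p = 0.235 with an estimated correlation) and secretory mRNAs (6 higher and 29 lower of 83, adjusted p = 4.5e-04, and adjusted p = 0.504 with an estimated correlation). KRAB zinc fingers were a further such list (1 higher and 12 lower of 37, adjusted p = 6.1e-04, and adjusted p = 0.366 with an estimated correlation). The common median left 7 higher and 6 lower for secretory mRNAs, 3 higher and 3 lower for metabolic ones and 2 higher and 2 lower for KRAB zinc fingers. It shifts all genes alike, so these lower calls depended on the scale. These lists passed the list test with the preset correlation alone.

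High on all 3 days in PE were RASD1 (3.74), MUC19 (3.69), EME2 (3.46 ± 0.16; chromosome 16, 1773207 to 1781708), MEGF6 (3.38), CPNE7 (3.38) and CACNA1H (3.31), and the noncoding MIR3648-2 (8.08), MIR212 (6.49) and SLC9A3-AS1 (3.26). NEAT1 was called higher in PE on days 3 (1.77) and 5 (1.72). PE had 1322, 2304 and 1825 higher and 5222, 373 and 148 lower on the 3 days, against 2681, 1179 and 888 higher and 2257, 720 and 393 lower with quantile normalisation and 2726, 1113 and 878 higher and 1773, 891 and 376 lower with a common median. Depth alone, drawn with no localisation, gave 470, 99 and 229 higher and 2827, 153 and 65 lower calls. With at least 5 expected reads 164 higher and 259 lower were called of 928.

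Localisation repeated between days. Genes called higher on all 3 days numbered 2076 in CE, 118 in ME, 4915 in SNE, 1514 in CBNE and 235 in PE, where independence of the days would give 60.4, 0.314, 836, 66.8 and 9.09. GAPDH and histone mRNAs in CE, mitochondrial transcripts in ME, MALAT1 and NEAT1 in SNE and SNORD3A in CBNE belonged to them. With a common median, chosen later, they numbered 3064 in CE, 687 in ME, 1142 in SNE, 1458 in CBNE and 159 in PE, and with at least 5 expected reads 177 in CE, 22 in ME, 61 in SNE, 34 in CBNE and 20 in PE. The level of a gene sets how easily it is called, and its effect on the overlap was not separated.

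Differentiation changed whole-cell RNA by day 3. ANKRD1, a stretch- and YAP-responsive gene, went from 0.0455 ± 0.0644 to 385 ± 41.3 TPM in INPUT (log2 8.52 ± 0.45), and ANXA1 (6.89), FLNC (6.33), PCAT14 (6.33), EMP1 (5.92) and SFTA1P (5.50) rose with it. The BMP response list rose for 16 of 19 (adjusted p = 6.1e-23), including MSX2 (5.55), NOG (5.52), GATA3 (4.81) and GATA2 (4.24). Matrix and transition genes gave 18 higher and 2 lower of 29, or 18 and 3 adjusted over the list alone (adjusted p = 7.1e-19), with LOX (5.61), TAGLN (3.60) and FN1 (3.22) up and THY1 (-1.55) and COL6A1 (-1.42) down. Cytoskeleton mRNAs MYL9 (2.58), VIM (2.07) and LMNA (1.89) rose (15 of 45, adjusted p = 3.4e-21), as did cell cycle inhibitors and p53 targets such as GADD45A (3.12; 11 of 21, adjusted p = 1.1e-09).

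Lineage genes had begun to move on day 3. Lateral and cardiac mesoderm genes gave 11 higher and 1 lower of 27, or 13 and 1 adjusted over the list alone (adjusted p = 3.0e-07), with BMP4 (4.70) and ACTC1 (4.47) up and KDR down (-2.26). Primitive streak genes rose for 8 of 27, or 9 adjusted over the list alone (adjusted p = 9.3e-05). Amnion and trophoblast genes, with TFAP2A at 5.64, rose for 9 of 26, or 11 adjusted over the list alone (adjusted p = 5.1e-08) and epithelial genes for 9 of 25 (adjusted p = 3.2e-08). Neural crest and surface ectoderm genes rose for 5 of 15, or 6 adjusted over the list alone (adjusted p = 1.2e-04) and endoderm genes for 5 of 14 (adjusted p = 0.00459). WNT targets gave 4 higher and 1 lower of 17, or 7 and 1 adjusted over the list alone (adjusted p = 8.2e-04). Immediate early genes such as CCN2 (2.67) gave 8 higher and 1 lower of 29, or 9 and 1 adjusted over the list alone (adjusted p = 8.3e-04, and adjusted p = 0.258 with an estimated correlation). Pluripotency genes gave 2 higher and 11 lower of 35 (adjusted p = 1.9e-08) and stem cell lncRNAs 1 higher and 7 lower of 14 (adjusted p = 2.2e-06). NPTX1 (-5.57), LINC00458 (-5.25) and JAKMIP2-AS1 (-4.86) were among those that fell most, and microRNA genes of the chromosome 19 cluster, such as MIR498 and MIR520E, were listed at 0 on day 3.

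By day 5 mesoderm genes had risen. HAND1, a transcription factor of lateral and cardiac mesoderm (chromosome 5, 154474972 to 154478264), stood at 0.740 ± 0.389 TPM on day 0, 30.9 ± 2.99 on day 3 and 787 ± 30.0 on day 5 (log2 8.84 ± 0.49, day 5 against day 0). TBXT went from 0.911 ± 0.210 to 66.3 ± 0.742 TPM (5.14 ± 0.42) and MIXL1 from 3.95 ± 0.0828 to 319.7 ± 18.3 (6.02 ± 0.64). Primitive streak genes rose for 21 of 27 (adjusted p = 1.2e-21), with APLNR (7.83), CER1 (7.67) and EOMES (6.26). The lateral and cardiac list gave 20 higher and 1 lower of 27, or 21 and 1 adjusted over the list alone (adjusted p = 6.8e-17), with MSX2 (6.74), TBX3 (6.68) and MSX1 (4.97) up and KDR down (-1.65). The paraxial (3 higher and 1 lower of 13, adjusted p = 0.0774) and haemato-endothelial lists (7 higher and 4 lower of 23, adjusted p = 0.160) did not pass. GATA4 was not called, at 0.891 ± 0.110 TPM on day 5.

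Signalling and matrix programmes rose alongside on day 5. The BMP response list rose for 16 of 19 (adjusted p = 1.6e-21). WNT targets rose for 12 of 17 (adjusted p = 5.8e-12), with SP5 (5.87), CDX2 (4.74) and DKK1 (4.71), and HOX genes for 6 of 10 (adjusted p = 2.7e-06). Matrix and transition genes gave 22 higher and 1 lower of 29, or 22 and 2 adjusted over the list alone (adjusted p = 4.8e-19), with LUM (5.60), FN1 (5.33) and SNAI2 (4.92) up. Immediate early genes such as KLF6 (2.98) rose for 15 of 29, or 16 adjusted over the list alone (adjusted p = 1.6e-09) and cytoskeleton mRNAs for 12 of 45 (adjusted p = 3.5e-12). Inhibitors and p53 targets such as CDKN2B (3.40) rose for 8 of 21 (adjusted p = 1.3e-06). Secretory mRNAs gave 23 higher and 4 lower of 83 (adjusted p = 4.0e-09, and adjusted p = 0.281 with an estimated correlation). TCIM (8.45), ANKRD1 (8.41) and DIO3 (6.81) rose most beside them. NEAT1 (3.45) and MALAT1 (1.59) rose and MIAT fell (-2.86), although the nuclear lncRNA list did not pass (adjusted p = 0.928).

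Markers of other lineages moved in the same libraries. Amnion and trophoblast genes rose for 22 of 26 (adjusted p = 9.9e-29), with TFAP2A, a surface ectoderm and trophoblast factor, at 0.151 ± 0.00941 TPM on day 0, 56.5 ± 2.90 on day 3 and 156 ± 1.93 on day 5 (7.09 ± 0.23), GATA3 (6.42) and DLX5 (6.26). Epithelial genes rose for 12 of 25 (adjusted p = 2.2e-14; KRT19 3.46) and endoderm genes for 7 of 14 (adjusted p = 1.5e-05; GATA6 4.69). Neural crest and surface ectoderm genes gave 8 higher and 1 lower of 15, or 9 and 1 adjusted over the list alone (adjusted p = 4.2e-08), with FOXD3 lower (-3.61). Neuroectoderm genes gave 2 higher and 5 lower of 17 (adjusted p = 0.408), with ZIC2 (-1.59) and ZIC5 (-2.64) lower.

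Pluripotency faded unevenly. PRDM14 fell from 104 ± 2.39 to 3.50 ± 0.355 TPM (-4.54 ± 0.16), and UTF1 (-4.93), USP44 (-3.94) and PIM2 (-3.86) fell too, whereas NANOG (-2.11 ± 0.32) and POU5F1 (-1.14 ± 0.32) fell less and NODAL (1.69), CDH1 (1.08) and EPCAM (1.04) rose. The list gave 3 higher and 20 lower of 35 (adjusted p = 1.8e-12). Of the stem cell lncRNAs 9 of 14 fell (adjusted p = 2.2e-08), led by LINC-ROR (-5.23) and LINC01108 (-4.51). IDO1 (-5.49), MT1G (-5.55) and LINC02335 (-5.32) were lower as well, and HES3 was listed at 0 on day 5.

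**Figure D3:**
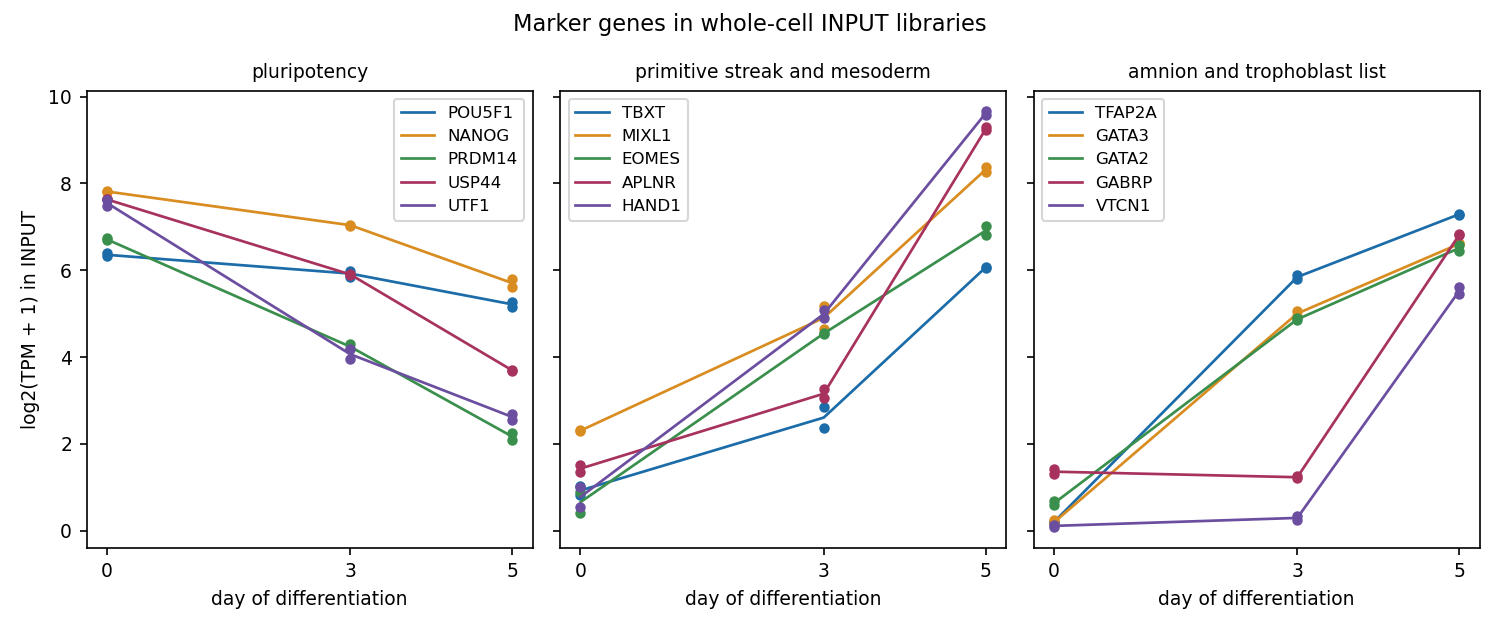
log2(TPM + 1) in INPUT on days 0, 3 and 5 of pluripotency, mesoderm, and amnion and trophoblast genes, with a point per library and lines through the means. HAND1 stood at 0.740 TPM on day 0, 30.9 on day 3 and 787 on day 5.

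Most housekeeping lists did not pass in INPUT. GAPDH was not called (5329 ± 7.65 TPM on day 0, 5473 ± 99.6 on day 5). Day 5 lists that did not pass were mitochondrial mRNA (adjusted p = 0.786), ribosomal proteins (adjusted p = 0.483), respiratory chain (adjusted p = 0.156) and metabolism (adjusted p = 0.209). Nor did histones (adjusted p = 0.881), stress (adjusted p = 0.520), KRAB zinc fingers (adjusted p = 0.653), centrosome and spindle (adjusted p = 0.467), or the noncoding lists of cytoplasmic lncRNA (adjusted p = 0.0936), snRNA (adjusted p = 0.851), snoRNA (adjusted p = 0.624) and structured RNA (adjusted p = 0.495). S and G2/M genes shifted down slightly as a list (median -0.35, adjusted p = 0.0351, and adjusted p = 0.589 with an estimated correlation).

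Between days 3 and 5 the amnion list (22 of 26, adjusted p = 2.6e-39; GABRP 5.59, VTCN1 5.23) and primitive streak list (18 of 27, or 19 adjusted over the list alone, adjusted p = 8.6e-30) rose furthest. HAND1 (4.63), TBXT (3.46), MIXL1 (3.42) and SOX17 (3.78) rose and NANOG fell (-1.33). Lateral mesoderm (10 of 27, or 13 adjusted over the list alone, adjusted p = 2.6e-13) and WNT lists (10 of 17, adjusted p = 9.2e-16) rose. HOX (5 of 10, adjusted p = 4.8e-09) and BMP lists (5 of 19, or 7 adjusted over the list alone, adjusted p = 1.2e-05) rose as well, and pluripotency (14 of 35, adjusted p = 2.7e-10) fell. Over all genes 1004 higher and 836 lower on day 3, 1521 higher and 1651 lower on day 5 against day 0, and 616 higher and 573 lower between days 5 and 3 were called, the last 777 higher and 417 lower with a common median. In the simulated data above most changes of INPUT were missed. A fit of INPUT libraries alone, added later, gave 1199 higher and 1271 lower on day 3 and 1750 higher and 2137 lower on day 5.

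Contrasts of extracts changed by day 5, measured as their difference between days. Library numbers in the labels jump between the day 5 ME replicates, and all day 5 SNE, CBNE and PE libraries follow the jump, so a batch of library making cannot be told apart from day 5 in these extracts. The ME replicates on either side of it had a Pearson's r of 0.94, against 0.93 on day 0 and 0.94 on day 3. VIM, an intermediate filament mRNA that rose in the cells, went from 53.2 to 467 TPM in ME and its ME contrast rose (1.35 ± 0.14). ACTB went from 179 to 568 TPM in ME (1.17 ± 0.11), with ACTN4 (1.68) and PFN1 (1.40). The ME contrast rose for 8 of 45 cytoskeleton mRNAs, or 10 adjusted over the list alone (adjusted p = 2.6e-14, camera). Immediate early mRNAs shifted with them, 12 of 29, or 13 adjusted over the list alone (adjusted p = 8.6e-13), among them JUND (2.04; 72.4 to 600.2 TPM), IER2 (1.89), ZFP36 (1.69) and CCN2 (1.65), and so did metabolic mRNAs (5 of 31, adjusted p = 1.2e-13) such as PKM (1.22).

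Other contrasts changed too. Structured RNA fell from 8.07% to 2.64% of PE and 45S genes from 6.58% to 0.624%. Whether RNA moved or recovery differed was not tested. In SNE ribosomal protein mRNAs fell for 11 of 74, or 12 adjusted over the list alone (adjusted p = 2.7e-14), such as RPS6 (-1.40) and RPSA (-1.26). Cytoplasmic lncRNAs fell there for 5 of 15, or 6 adjusted over the list alone (adjusted p = 3.1e-04), namely GAS5 (-1.33), DANCR (-1.25), SNHG5 (-1.06) and SNHG29 (-1.02) among others. In CE the contrasts of newly expressed genes rose, for primitive streak 9 of 27 (adjusted p = 1.4e-13; DKK1 2.40, TBXT 1.79) and HOX 5 of 10 (adjusted p = 4.0e-08). Lateral mesoderm genes rose there for 5 of 27, or 6 adjusted over the list alone (adjusted p = 7.4e-06; MSX1 3.18), as did histones for 4 of 34 (adjusted p = 8.5e-05). Genes near 0 on day 0 have no measured localisation there, so these CE changes rest mainly on day 5 values. In PE SNORD3A fell from 88683 to 13186 TPM (-3.00 ± 0.18; list 3 of 4, adjusted p = 1.2e-06), while NEAT1 rose in PE (1.96) and SNE (1.08) and fell in CE (-1.68).

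Day 3 changes followed a similar course in ME, where ACTB rose (1.09) with cytoskeleton (6 higher and 2 lower of 45, or 7 and 2 adjusted over the list alone, adjusted p = 1.4e-11) and metabolic mRNAs (4 of 31, adjusted p = 1.4e-19). In CBNE mitochondrial (13 of 13, adjusted p = 1.3e-19), histone (16 of 34, adjusted p = 8.3e-09) and ribosomal protein mRNAs (1 higher and 38 lower of 74, adjusted p = 1.9e-25) fell.

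Counts of changed genes depended on scale and depth. On day 5 they were 304 higher and 2140 lower in CE, 728 higher and 771 lower in ME, 571 higher and 762 lower in SNE, 1314 higher and 3426 lower in CBNE and 7565 higher and 570 lower in PE, where the median gene moved by -0.56, -0.07, -0.06, -0.13 and 0.87. With a common median they were 1262 higher and 389 lower in CE, 958 higher and 524 lower in ME, 1948 higher and 2735 lower in CBNE and 1915 higher and 2767 lower in PE. Quantile normalisation gave 872 higher and 604 lower in CE, 626 higher and 506 lower in SNE, 2324 higher and 2461 lower in CBNE and 2300 higher and 2631 lower in PE. Without structured and mitochondrial RNA there were 413 higher and 3183 lower in ME and 2489 higher and 2732 lower in CBNE. On day 3 they were 109 higher and 2356 lower in CE, 242 higher and 1095 lower in ME, 186 higher and 939 lower in SNE, 3126 higher and 1203 lower in CBNE and 6855 higher and 317 lower in PE. The common median turned those into 910 higher and 271 lower, 624 higher and 348 lower, 416 higher and 258 lower, 1288 higher and 2198 lower and 1231 higher and 2359 lower in that order. Quantile normalisation gave 389 higher and 454 lower, 573 higher and 702 lower, 360 higher and 207 lower, 1537 higher and 1726 lower and 1631 higher and 1675 lower. Totals without structured and mitochondrial RNA gave 213 higher and 2997 lower in ME and 225 higher and 418 lower in SNE. Lineage genes lower in day 5 CBNE were nearly all under 5 expected reads and are treated in the closing section.

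PolyA RNA of day 0 separated nucleus from cytoplasm for the same lncRNAs. MALAT1 stood at 614 ± 4.47 TPM in the nucleus and 14.5 ± 0.0787 in the cytoplasm (log2 5.30 ± 0.04), and NEAT1 was higher in the nucleus (2.45 ± 0.11), as was the microRNA host MIR17HG (4.53). The cytoskeleton mRNA SPTAN1 (4.38) was nuclear too. The cytoplasm held MT-ND2 (-2.19 ± 0.02), CYSTM1 (-2.47), PFDN1 (-2.35), EIF4EBP1 (-2.21), GNG5 (-2.19), TOMM22 (-2.17), NDUFA1 (-2.14) and POU5F1 (-2.06). Mitochondrial RNA took 15.3% ± 0.213 of the cytoplasm and 7.30% ± 0.0888 of the nucleus, lncRNA 1.64% ± 0.0218 and 4.21% ± 0.00498 (n = 2 each, not tested).

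Some lists passed in polyA RNA with the preset correlation. Mitochondrial mRNA leaned to the cytoplasm for 10 of 13 (adjusted p = 2.4e-11, and adjusted p = 0.576 with an estimated correlation), and ribosomal proteins gave 2 nuclear and 24 cytoplasmic of 75 (adjusted p = 7.9e-21, and adjusted p = 0.755 with an estimated correlation). The same lean was seen for respiratory chain (1 nuclear and 24 cytoplasmic of 49, adjusted p = 6.2e-17, and adjusted p = 0.755 with an estimated correlation) and metabolism (1 nuclear and 7 cytoplasmic of 33, adjusted p = 1.5e-09, and adjusted p = 0.576 with an estimated correlation). Secretory mRNAs such as HSPG2 (2.96), FN1 (2.89) and LRP1 (2.81) leaned to the nucleus for 46 of 83 (adjusted p = 1.3e-08, and adjusted p = 0.755 with an estimated correlation). Centrosome and spindle mRNAs such as ASPM (3.68) and CENPF (3.30) did so for 18 of 21 (adjusted p = 5.8e-05, and adjusted p = 0.755 with an estimated correlation). Nuclear too were the lists of nuclear lncRNA (7 of 8, adjusted p = 0.00289, and adjusted p = 0.736 with an estimated correlation) and KRAB zinc fingers (18 of 36, adjusted p = 1.6e-04, and adjusted p = 0.755 with an estimated correlation). All kept their direction under a common median. In all 5005 genes were called higher in the nucleus and 1037 in the cytoplasm, 2668 and 2489 with a common median and 2346 and 2421 with quantile normalisation. Totals without structured and mitochondrial RNA gave 4497 and 1318, so the surplus of nuclear genes was kept there and lost where values or medians were aligned (median gene 0.36). The fit had only 2 residual degrees of freedom.

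The tables met in part. Across 15775 genes the nuclear extracts over the cytoplasmic extracts of total RNA and polyA nucleus over cytoplasm had a Pearson correlation of 0.41 (Spearman 0.37), and across 5754 genes at a mean of at least 4 in both 0.50. Of 991 genes called higher in polyA cytoplasm, 697 were called higher in CE, where independence would give 247. Of 4583 higher in polyA nucleus, 2672 were higher in SNE (2168 by independence) and 378 in CE (1142). CBNE shared 697 with polyA nucleus (640.3), PE 429 (263) and ME, an extract outside the nucleus, 217 (129). MALAT1 and NEAT1 in the nucleus, and NDUFA1 and POU5F1 in the cytoplasm, were placed alike by both.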

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

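Tests here that were chosen after the result was seen were the repeat on day 3, the draws with no localisation, the repeat between replicates, the snoRNA scale, and the members of other lists and the median gene for the amnion genes, while those of olfactory receptors and exon GC were set beforehand. The contrasts of an extract differed between days for many genes, by a test of the difference itself (the interaction of extract and day). For day 3 against day 0 the genes called were 2465 in CE, 1337 in ME, 1125 in SNE, 4329 in CBNE and 7172 in PE, and for day 5 2444, 1499, 1333, 4740 and 8135. The counts in CBNE and PE were the largest, and there depth also differed most between days, 37037 to 47216 reads in day 0 PE against 290303 to 471910 in day 5 PE.

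The same test picked out lists whose members moved together between days 0 and 5, given as the median log2 difference. In CE these were primitive streak (1.32), HOX (1.02), paraxial mesoderm (0.65; MSGN1 4.12), lateral mesoderm (0.54), definitive endoderm (0.32), histone (0.28) and haemato-endothelial genes (0.16). In ME they were immediate early (1.14), metabolic (0.70), haemato-endothelial (0.66), cytoskeleton (0.61) and histone mRNAs (0.41). In SNE they were cytoplasmic lncRNA (-0.92), ribosomal protein (-0.63) and neural crest genes (0.49), and in PE snoRNA (-3.10). CBNE gave primitive streak (-2.08), amnion and trophoblast (-1.64), neural crest (-1.55), lateral mesoderm (-1.49), BMP response (-1.40) and haemato-endothelial genes (-0.83). Most of these lineage genes rose in INPUT but had under 5 expected reads in day 5 CBNE, where many were listed at 0, so their contrast there measures the floor of the library.

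Single genes with the largest differences between days 5 and 0 were mostly short. In CBNE they were MIR27A (7.46), MIR23A (7.37), MT-TT (6.62), MT-TN (-9.39), TCIM (-10.13) and MT-TR (-11.39). In CE they were AC099791.2 (4.39), MT-TN (4.07), AL713998.1 (3.97), AC125807.2 (-4.66), MIR563 (-4.83) and RNU6-367P (-5.65), and in ME MIR200B (7.59), MIR200A (5.31), G0S2 (3.84), MIR4675 (-5.25), MIR645 (-5.35) and MIR378H (-5.87). In PE they were MT-TR (10.69), MT-TI (9.61), MIR4746 (9.09), MIR1303 (-6.53), MIR200B (-6.58) and MIR200A (-7.42), and in SNE MIR200A (5.31), AL713998.1 (4.16), AL645608.7 (3.16), GCSHP5 (-4.69), AC090498.1 (-6.23) and MIR320A (-6.69). These are differences of log2(TPM + 1) contrasts that include libraries listing the gene at 0, and are neither folds nor bounds.

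Genes outside the tested classes, unused by the class comparison, took a large part of some libraries. MicroRNA genes made up 7.34% ± 0.849 of day 0 CBNE against 0.706% ± 0.0314 of INPUT, and genes of no class 9.51% ± 0.0365 against 0.265% ± 0.00435. A single unnamed transcript, AL357562.1 (chromosome X, 122242008 to 122242616), accounted for 9.27% of day 0 CBNE, and the microRNA gene CR392039.1 of chromosome 21 for 2.94%. Genes of under 100 bases gain a high TPM from a few reads.

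Genes near 0 in INPUT appeared at several TPM in CBNE. Of 2979 genes called higher in day 0 CBNE, 641 had under 1 TPM in INPUT, at a median of 5.34 TPM in CBNE. Genomic DNA, GC content and low depth cannot be told apart as its cause: the lowest ratio of CBNE to INPUT for summed olfactory receptor genes was 0.864 over the 3 days but 4.73 on day 0, the lowest Spearman correlation of exon GC with the PE contrast was 0.109 over the 3 days, and 42.6% of the 641 genes were called higher again in CBNE on day 3, against 19.7% of all tested genes. The correlation with the CBNE contrast was 0.23, 0.33 and 0.09 on days 0, 3 and 5, and for PE 0.32 on day 0 (day 0 PE and CBNE 0.63 and 0.44 among genes with at least 5 expected reads), and the 641 genes had a median exon GC of 52.6% against 49.4% for all tested genes. No test met either of its bounds on every day, and the sum for the receptors rests on few reads in CBNE. No biological explanation was tested.

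Most called genes of day 0 CBNE and PE were called lower, 6149 in CBNE and 5222 in PE. Low depth accounts for much of this among genes under 5 expected reads, since libraries drawn with no localisation gave at least 56.7% as many lower calls in these extracts. Among genes with at least 5 expected reads it cannot be the whole cause, since low values repeated between replicates. Of the 928 such genes, called or not, those at least 2-fold under the other extracts in replicate 1 were so in replicate 2 in 88.9% of cases in CBNE and 83.0% in PE, against 7.05% and 20.98% of the rest, with each replicate set against libraries of its own number. Within bins of expected reads the gap was at least 61.8 percentage points, where libraries drawn with no localisation gave 2.26 in CBNE and 2.03 in PE. The draws gave 13 lower calls among them in CBNE against 390, and in PE 6 against 259. GAPDH (log2 -1.89 in CBNE) and histone mRNAs such as H2BC8 (-5.61) belong to the latter part. A scale set by abundant snoRNA cannot be the whole cause either: at 15.2% of CBNE and 10.9% of PE it changes the log2 value of every other gene by -0.24 at most, where a call needs a change of 1. The overall scale mattered most in PE, where a common median left 1773 lower calls and quantile normalisation 2257, against 6035 and 4128 in CBNE. The nature of the extract, loss to nuclease and a scale set by other RNA stay open.

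Amnion and trophoblast genes rose in INPUT by day 5 beside mesoderm genes. Of the members held by no other list 77.8% rose. The lower quartile over all tested members lay 1.96 in log2 above the median gene, which itself moved by -0.09. With 22 of 26 members called higher, both values had to pass their bounds, so neither is a separate test of shared members or of scaling. They show only that the rise was not confined to shared members and that the median gene did not rise with them. GATA3 and TFAP2A rose with GABRP and VTCN1. Whether such cells stood beside mesoderm cells in the culture, or the same cells carried both programmes, cannot be read from bulk RNA and stays untested, as does any effect of replicate cultures.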

How the results depend on the processing

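Among the tests below, those that kept genes with at least 5 expected reads, used 1/2 read as pseudocount, gave each group its variance, left out the CBNE or CBNE and PE libraries, took INPUT libraries only, took SNE over CE only, or took the overlap under a common median or the read minimum, were chosen after the results were seen. Counts below add higher and lower calls and are called kept within 1.5 times the original count. Without a filter on low values all 29 counts were kept. So were 15 with libraries of the same day only, 3 with INPUT libraries only and the overlap at an adjusted p under 0.01 (7999 genes). Class shares without mitochondrial-encoded genes gave 17 calls of 45, a count like the original 16, but not the same calls. Those of lncRNA (adjusted p = 0.470) and protein-coding RNA (adjusted p = 0.187, turned in direction) in ME were lost, and protein-coding RNA (adjusted p = 2.0e-04) and histone mRNA (adjusted p = 0.0378) in CBNE, snRNA in ME (adjusted p = 0.0308), structured RNA in SNE (adjusted p = 0.0378) and rRNA genes in CE (adjusted p = 0.0284) were gained. The calls of HAND1 (log2 8.55 with quantile normalisation) and MIXL1 (5.99) in INPUT on day 5 stood under each scaling.

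Replicate numbers gave little sign of pairing, which cannot be excluded. Residual correlations between libraries of the same number had a median of -0.02 on day 0, 0.02 on day 3 and 0.04 on day 5. The highest were 0.29, 0.26 and 0.22 on these days and 0.24 for INPUT across days, with 5 of 15 pairs above 0.1 on day 5. With the number as a block all 29 counts were kept, for example 6730 in day 0 CE, 9129 in day 0 CBNE and 3164 in INPUT, day 5 against day 0. Among named genes the block ended the call of MIR645 in ME (day 5 against day 0) and changed no other call.

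Scaling moved several counts, and the cause was not tested beyond what each scaling does to the median gene. Quantile normalisation kept 19 and moved day 0, 3 and 5 SNE to 5738, 4181 and 5373, day 3 ME to 2744, day 5 PE to 1281, and changes by day 3 to 843 in CE, 567 in SNE and 3306 in PE and by day 5 to 1476 in CE and 4931 in PE. A common median moved day 5 PE to 1254 and changes by day 3 to 1181 in CE, 674 in SNE and 3590 in PE and by day 5 to 4682 in PE. Totals without structured and mitochondrial RNA moved ME to 4556 on day 0 and 3047 on day 3, and changes to 3210 (day 3) and 3596 (day 5) in ME, 1597 in CE and 643 in SNE (both day 3).

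Low values limited the calls. A pseudocount of 0.1 gave 4104 and 3215 genes in day 3 and day 5 PE and 2218 changes in ME by day 3, and a variance for each group 4092 and 1086 in day 0 and day 5 PE, 1595 changes in CBNE by day 5 and 1690 in SNE by day 3. INPUT as the reference left 172 genes in day 0 CE. With at least 5 expected reads far fewer genes were tested, and calls in CE, ME, SNE, CBNE and PE were 564, 304, 427, 583 and 423 on day 0, 1588, 916, 1013, 1922 and 470 on day 3 and 334, 94, 187, 444 and 111 on day 5, changes 376, 116, 35, 284 and 400 by day 3 and 162, 107, 51, 211 and 291 by day 5, INPUT day 5 against day 0 2039, and genes higher on all 3 days 314 in place of 8858. The same genes with 1/2 read as pseudocount gave 561, 294, 435, 561 and 405, 1657, 969, 1041, 1943 and 509, and 331, 85, 198, 432 and 93 on the 3 days, and changes of 374, 154, 49, 294 and 380 by day 3 and 171, 122, 51, 171 and 283 by day 5.

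Leaving out the CBNE and PE libraries gave 4841 genes in day 0 ME and 2462 in day 3 ME, and changes of 1348 and 1457 in CE (days 3 and 5), 746 in ME (day 3) and 2040 in SNE (day 5). Leaving out CBNE alone gave 4747 in day 3 PE. Of 435 list tests 137 passed with an estimated correlation. The correlation of total with polyA RNA rose to 0.50 for genes at a mean of at least 4 and to 0.50 for SNE over CE only. The cause of these moves was not tested.

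Leaving out each library in turn, with the lone sample assumed to vary like the other groups, the counts in CE, ME, SNE, CBNE and PE ranged over 5960 to 6919, 2462 to 3279, 9443 to 10597, 8911 to 9320 and 5308 to 7726 on day 0, 6402 to 7521, 4216 to 4958, 6084 to 6773, 9136 to 9751 and 2522 to 2781 on day 3 and 6548 to 7682, 3109 to 3915, 8148 to 9378, 10503 to 11090 and 1699 to 2706 on day 5. Changes ranged over 1633 to 3190, 968 to 1863, 729 to 1609, 4109 to 5549 and 5741 to 8685 by day 3 and 1955 to 3088, 912 to 1917, 1052 to 1642, 4507 to 5430 and 6057 to 9427 by day 5, INPUT over 1504 to 1678 (day 3 against 0), 2818 to 2877 (day 5 against 0) and 984 to 1084 (day 5 against 3), and polyA RNA over 4836 to 6183. Counts moved by more than 1.5 times without day 0 SNE replicate 2 (changes in SNE by day 3), day 3 CE replicate 1 (changes in CE by day 3) and day 5 ME replicate 1 (changes in ME by day 5), whose library number precedes a jump in the numbering that replicate 2 follows. With either replicate number left out the exact test of class shares had 125 permutations and 0 calls in each case, with 12 of 50 at an unadjusted p under 0.05 and a lowest p of 0.00800, since so few permutations allow no smaller value.

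Some named genes changed direction, all of them at low levels or against another reference, and the cause was not tested. HAND1 in day 3 ME went from 1.09 to -0.12 and in day 3 SNE from 0.21 to -1.17 without the CBNE and PE libraries, and its change by day 5 from 0.53 to -2.53 in PE and from -0.44 to 1.82 in SNE with 1/2 read as pseudocount. MIXL1 in day 0 PE went from 0.32 to -1.21 without day 0 PE replicate 1 (and to 1.86 without replicate 2). With INPUT as the reference NANOG went from 0.33 to -1.13 in day 0 ME and from 0.28 to -1.17 in day 0 SNE, and POU5F1 from 0.46 to -2.06 in day 0 PE. TBXT in CBNE (change by day 5) went from -1.58 to 0.38 with a pseudocount of 0.1. Alternatives set beforehand for read counts were not run, since the tables hold TPM, and each had a TPM alternative that was run. Depth limited CBNE and PE most.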

Other observations

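MT-ND6, the only mRNA encoded on the light strand of the mitochondrial genome, was divided between extracts unlike the other 12. The values of this part were looked at after the main results were seen. Of the summed TPM of the 13 mitochondrial mRNAs on day 0 it made up 10.99% ± 0.112 in SNE, 2.72% ± 0.0318 in ME, 1.06% ± 0.0245 in CE, 4.06% ± 0.267 in CBNE, 2.47% ± 1.05 in PE and 2.92% ± 0.187 in INPUT. On day 3 it was 5.67% ± 0.0241 in SNE, 8.20% ± 0.353 in PE and 4.42% ± 1.41 in CBNE, and on day 5 8.79% ± 0.853, 6.49% ± 0.716 and 2.57% ± 0.519, so SNE held the largest share on days 0 and 5 and PE on day 3. The 10 genes annotated in the 45S ribosomal DNA units of chromosome 21 took 4.84% ± 0.809 of day 0 CBNE and 6.58% ± 1.52 of PE, against 0.0255% ± 0.00188 of INPUT and 0.0131% ± 5.7e-04 of CE, and 7.45% ± 1.27 of day 5 CBNE. In day 0 CBNE all of this came from the lncRNAs FP236383.3 (26913 TPM) and FP671120.4 (21171 TPM). Outside the 10, MIR3648-2 (1.11%) and CR392039.1 (2.94% of day 0 CBNE) are spaced on chromosome 21 like MIR3648-1 and FP671120.2 of these units. They may be a further copy, so the 45S share may be too low.

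Length went with nuclear polyA RNA. Across 8061 protein-coding genes at a mean log2 value of at least 4 the union exon length correlated with the log2 ratio of nucleus over cytoplasm at a Spearman rho of 0.50, with medians of -0.48, 0.07, 0.39 and 0.76 from the shortest to the longest of 4 groups of genes of equal size, while GC content gave 0.01. SPTAN1 among the nuclear mRNAs is long, and NDUFA1 and GNG5 among the cytoplasmic ones short. In total RNA the SNE contrast went with low exon GC, at a rho of -0.44 on day 0, -0.51 on day 3 and -0.41 on day 5. Summed TPM of olfactory receptor genes was 236 ± 32.0 in day 0 SNE and 56.3 ± 7.49 in INPUT.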
